A study of Homo sapiens with 18 samples.

How the data were processed

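RNA was measured in 18 libraries of MB135 cells, an immortalized human myoblast line that carries a doxycycline-inducible, codon-altered DUX4 transgene (DUX4 is a transcription factor of the early embryo that is toxic to muscle). The labels give 6 lines with 3 libraries each: unedited cells (WT), a KLF18 knockout line (KO1), and knockout cells with an inducible tagged KLF18 at the AAVS1 safe-harbour locus, in a Short form (clones 1 and 2) and a Long form (clones 1 and 2). Every library is labelled as treated with 0.25 µg/mL doxycycline for 18 h, and no untreated library was analysed here. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 3 libraries of a line came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels' protocols give poly(A)-selected, stranded libraries read as 150 bp pairs.

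Per the submitters' processing notes, the tools included Trim Galore 0.6.7, featureCounts (listed as version 2.18.0) and DESeq2 1.44.0, with genome build GRCh38. The aligner, the annotation release, the strand setting and the handling of reads that fit several places are not given in the sources used here. The deposited table holds 18559 genes with a normalized signal per library, which is the read count divided by the library's size factor, rounded by the authors to 2 decimals. It also holds the authors' mean signal over all libraries, the authors' log2 fold changes and the authors' adjusted p-values for 11 comparisons between lines. The smallest mean signal was 9.18, so genes with few reads had been left out by the authors and cannot be called here. This mean runs over all lines, most of which are clones with added KLF18. Genes expressed only in clones could thus pass more easily than genes expressed only in WT or KO1. KO1 libraries had 165 to 248 of the listed genes at 0 reads, and clone libraries 2 to 18. No gene of the mitochondrial genome was analysed, which removes that check of RNA quality.

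Values of each library were whole multiples of 1 step, so the reads behind them were recovered: 100% of the values were whole within 0.0075 normalized counts. Recovered reads in the listed genes ranged from 30.9 M to 52.4 M per library. At this depth counting error is small for abundant genes, and it dominates where a line has a few reads. For a line with 1 to 3 reads, the ratio is given with an exact Poisson 95% interval of those reads, with the mean of the higher group taken as known. It covers counting error only, and PCR copies were not told apart. Where a group had 0 reads, the fold is a lower bound against a floor of 3 reads over the group.

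Because the values are normalized and not raw counts, the main test was limma 3.58.1 (limma-trend, R 4.3.3) on log2(value + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount makes fold changes of low genes smaller. The design written before the data were examined named this test for normalized values and edgeR for raw counts. All 18 libraries entered 1 fit with a group per line and no covariate, so that the lines share an estimate of spread. Contrasts were KO1 against WT, the mean of both clones of a form against KO1, the mean of both Long clones against the mean of both Short clones, and clone 2 against clone 1 within each form. A log2 fold change of a form is a mean over clones on the log scale, so it can differ from the ratio of the mean counts. No further expression filter was applied, since a filter on a total above 0 removes no gene here.

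Of 27 gene lists fixed before the data were examined, 26 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Counts within a list use adjusted p-values over all genes, and are also given adjusted over the list alone. Named genes followed a rule fixed at the same time. KLF18 and DUX4 are named where measured. Each comparison gives the 12 largest rises and the 12 largest falls among named genes that are neither pseudogenes nor LOC entries. These needed adjusted p under 0.05, a log2 fold change of at least 1, a mean of at least 1 CPM in the higher group, and clones of the compared lines on separate sides. Each described list gives up to 4 members by smallest adjusted p and members that go against the list. A few genes that meet these rules are not reported here. Lists described are those past the set test and the DUX4 target, KLF and SP family, myoblast, muscle differentiation and fibroblast lists.

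Gene identifiers were looked up in GENCODE 29 (GRCh38), where 18130 were found, 2161 of them with the same version. Coordinates are from that annotation. Reads of near-identical genes (the PRAMEF, TRIM, RFPL4, ZSCAN5, DEFB103 and SPDYE families, ALPG with ALPP, and TPRX1 with TPRX2) may be split between copies by the counting, and values of single members are uncertain. The same holds for overlapping and antisense genes such as HOXB-AS4, PCDH10-DT, CXXC4-AS1, POT1-AS1 and FXYD6-FXYD2.

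The fit was tested on counts simulated for the 18559 genes from the WT means and the spread within lines, with 200 changed genes. The changed genes were drawn only above a minimum mean count, so recovery was not tested for the lowest genes. For KO1 against WT it recovered 91.0% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 5 false calls. For Long against Short the shares were 92.5%, 98.5% and 100%, with 16 false calls. These were 7.6% of the simulated calls, against 2.6% for KO1 against WT. The simulated clones of a form did not differ from each other, so these false calls do not cover differences between clones. Replicates were compared with sampling noise: chi-square per degree of freedom lay between 1.63 and 4.26 over the 18 pairs of libraries within a line, so no pair agreed within sampling noise and no library was merged.

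Alternatives fixed before the data were examined were pseudocounts of 0.1 and 10, a stricter filter (a normalized count of at least 100 in 3 libraries), the replicate number as a block, a 2-fold threshold, an adjusted p of 0.01, each library left out, fits on the compared lines alone, 1 mean profile per clone, 6 libraries against 6, each clone pair, each clone against KO1, and the authors' calls. Tests on recovered reads (edgeR 4.0.16 with TMM or with DESeq2 size factors, and DESeq2 1.42.0), scaling to library totals or with TMM, a fit without Long clone 1, and comparisons with separate KO1 libraries on each side were chosen after seeing the data. The edgeR and DESeq2 tests had been listed beforehand for raw counts only.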

Results

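The series compared an MB135 myoblast line labelled as a knockout of KLF18, a KLF-family zinc-finger gene, with unedited cells and with knockout cells given a Short or a Long form of KLF18, all while DUX4 was induced. The table gave 18559 genes in 6 lines of 3 libraries each. Recovered reads per library were 32.2 to 39.6 M in WT, 31.9 to 52.4 M in KO1, 30.9 to 37.4 M in the Short clones and 33.9 to 41.6 M in the Long clones. The 10 most abundant genes took 6.7% to 8.1% of the reads. DUX4 was not analysed here, since 0 rows carry that symbol.

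KLF18 RNA was higher in KO1 than in WT, and higher again in every re-expressing clone. KLF18 (chromosome 1, 44137821 to 44141631, minus strand, GRCh38) had 8137 ± 337 normalized counts in WT and 15030 ± 550 in KO1 (SD, n = 3 each), 1.85 times the WT level. The level was 70026 ± 3636 in Short clone 1, 41473 ± 328 in Short clone 2, 113516 ± 1969 in Long clone 1 and 72663 ± 1547 in Long clone 2 (SD, n = 3 each). Both Long clones had higher means than both Short clones, but Long clone 2 was at only 1.04 times Short clone 1. Single libraries of these clones overlapped, with 74134 in Short clone 1 replicate 2 and 71834 in Long clone 2 replicate 2. The counts are not corrected for the length of a form. Reads of the added KLF18 were not told apart from those of the cell's own gene. The labels do not say which part of the gene was edited, so this RNA level does not check the knockout label. The neighbouring KLF17 (44118850 to 44135140, plus strand), a KLF gene of the early embryo, fell from 2407 ± 15 in WT to 397 ± 45 in KO1 and stood at 2879 to 3709 in the clones.

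**Figure D1:**
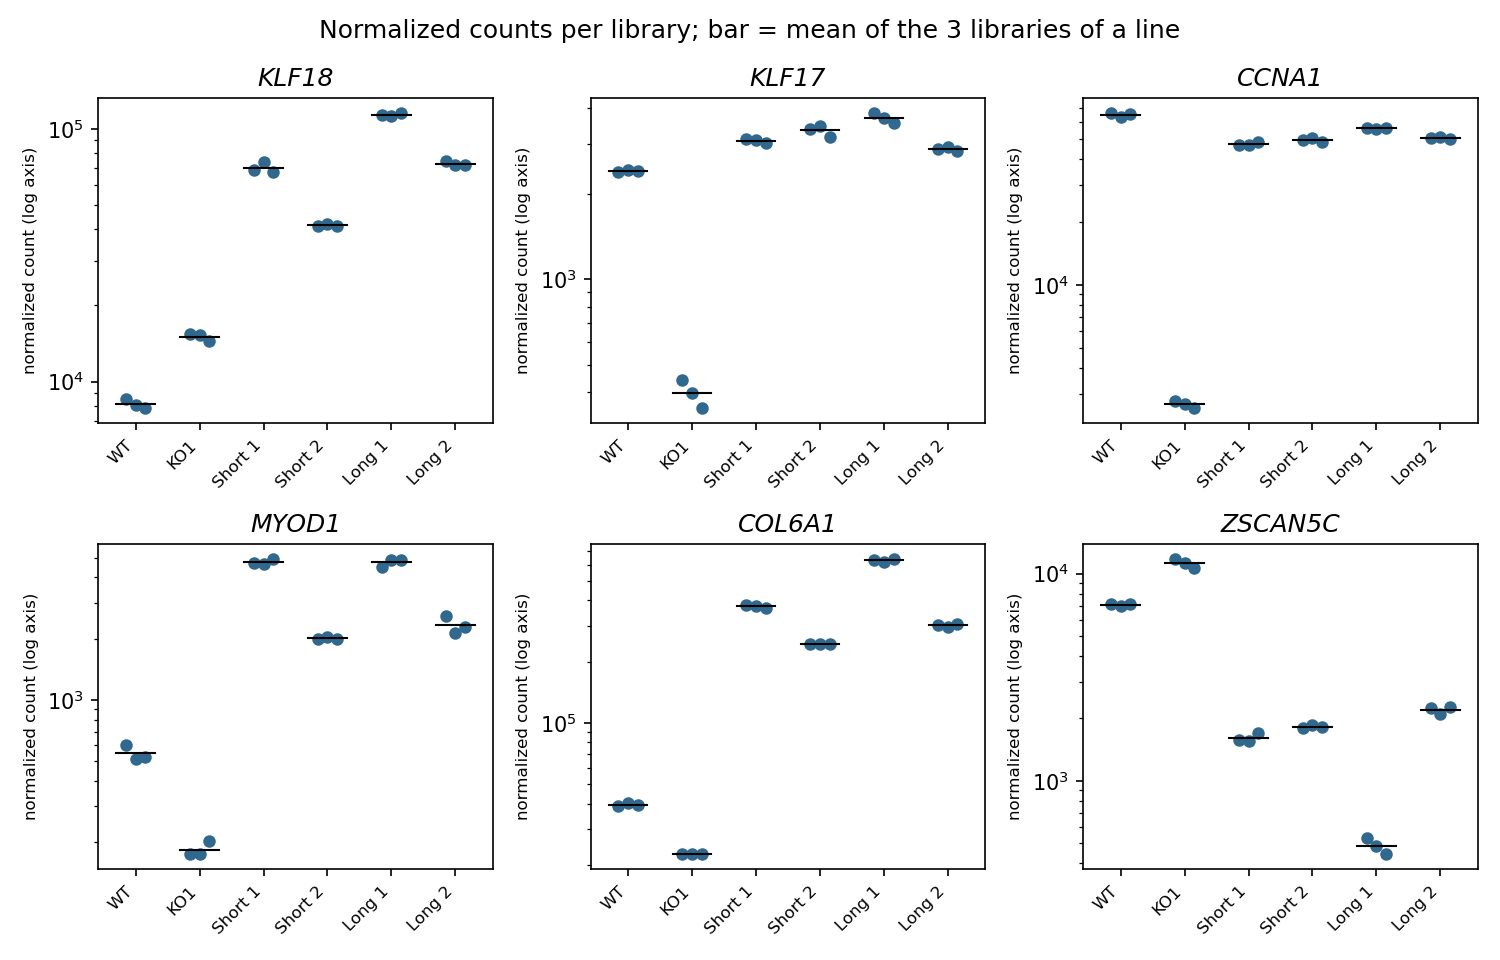
Normalized counts (log axis) of KLF18, KLF17, CCNA1, MYOD1, COL6A1 and ZSCAN5C, with a point per library and a bar at the mean of the 3 libraries of each line. KLF17 and CCNA1 were low in KO1 only, and ZSCAN5C was lower in every re-expressing clone than in WT and KO1.

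The line labelled as the knockout, KO1, was compared with WT. Among the largest falls, CCNA1, a germ-cell cyclin, went from 65191 to 2682 normalized counts (log2 fold change -4.60, SE 0.03, adjusted p = 9.98e-30). CA2, a carbonic anhydrase, fell from 2511 to 55.0 (log2 fold change -5.50, SE 0.08), and ALPG, a germ-cell alkaline phosphatase, from 698 to 14.6 (-5.48, SE 0.05). The other largest falls were SLC17A9, GPX7, MEG3, ALPP, INSM1, TC2N, ZNF43, PAX7 and FOXI3, with log2 fold changes between -5.17 and -3.96. PAX7, a transcription factor of muscle stem cells, went from 56.4 to 3.01 normalized counts. Of the largest rises, the protocadherin gene PCDH10 went from 356 to 11634 normalized counts (log2 fold change 5.03, SE 0.04) and PCDH19 from 163 to 2486 (3.94, SE 0.10). MS4A6E rose most (5.44, SE 0.32), and PCDH10-DT, NALF1, EBI3, VNN1, CNKSR2, KRT17, PLXDC1, PADI2 and TMEM178B rose by 2.72 to 4.35 on the log2 scale. In all, limma called 10401 genes, 5157 higher and 5244 lower, of which 649 were higher and 506 lower by at least 2-fold. Each side is a single line, so KLF18 and any other difference between these lines are compared together. The authors' deposited table calls 9058 genes for this pair, with 340 higher and 370 lower by at least 2-fold. The authors' fold change was smaller than the ratio of mean counts for 83.0% of genes with a 2-fold ratio.

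Cell-cycle genes were lower in KO1 and p53 target genes higher. Of 38 genes of S phase and mitosis, 36 fell and 1 rose (36 and 1 adjusted over the list alone; camera adjusted p = 1.58e-21, and adjusted p = 0.0149 with an estimated correlation). CDC20 fell most clearly (log2 fold change -2.54, SE 0.04), with TOP2A (-1.16, SE 0.03), UBE2C (-0.85) and CCNB1 (-1.01), while CCNE1 rose (0.11). Of 30 p53 targets, 24 rose and 2 fell (24 and 2 adjusted over the list alone; camera adjusted p = 4.53e-08, and adjusted p = 0.0149 with an estimated correlation), with GDF15, RRM2B (0.70, SE 0.03), MDM2 (0.70) and SPATA18 (1.60) leading and ZMAT3 (-0.16) and BTG2 (-0.31) lower. Replication-dependent histone genes, whose RNA mostly lacks a poly(A) tail, rose in 9 of 13 cases and fell in 0 (9 and 0 adjusted over the list alone; camera adjusted p = 0.00259, and adjusted p = 0.0323 with an estimated correlation). H2BC12 (1.13, SE 0.05), H2AC6 (0.81), H2BC4 (0.61) and H1-2 (1.02) led that list.

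Interferon-stimulated genes rose in 28 of 33 cases and fell in 0 (28 and 0 adjusted over the list alone; camera adjusted p = 1.07e-07), led by HERC5 (log2 fold change 1.43, SE 0.08), MX2 (2.04) and BST2 (2.25). That call was lost with an estimated correlation (adjusted p = 0.301). MHC class I presentation genes rose in 12 of 15 cases (12 adjusted over the list alone; camera adjusted p = 0.000333, but adjusted p = 0.233 with an estimated correlation), with HLA-C (0.97), HLA-B (1.02) and B2M (0.77) higher, NLRC5 (-0.37) lower, and ERAP1 (-0.12) lower except without WT replicate 3 (-0.09), KO1 replicate 2 (-0.11) or KO1 replicate 3 (-0.09), where it missed the threshold. Cholesterol synthesis genes rose in 17 of 22 cases and fell in 2 (18 and 2 adjusted over the list alone; camera adjusted p = 0.000651, but adjusted p = 0.233 with an estimated correlation). MSMO1 (0.67), STARD4 (0.54) and IDI1 (0.41) led, and FDPS (-0.20) and ACAT2 (-0.22) fell. Immediate early genes fell in 12 of 20 cases and rose in 3 (12 and 3 adjusted over the list alone; camera adjusted p = 0.00249, but adjusted p = 0.314 with an estimated correlation), with MYC (-1.55, SE 0.03), EGR1 (-0.98), FOSL1 (-1.08) and ATF3 (-0.58) lower and FOSB (0.42) higher. Heat shock genes fell in 9 of 15 cases and rose in 5 (9 and 5 adjusted over the list alone; camera adjusted p = 0.0192, but adjusted p = 0.348 with an estimated correlation). HSPA6 (-1.39), HSPH1 (-0.84), HSPA1B (-0.75) and HSPA1A (-0.78) fell, whereas HSPA4L (0.37), CRYAB (1.55), DNAJA1 (0.26) and BAG3 (0.17) rose. The fit of list heat_shock KO1 vs WT gave adjusted p = 0.0509 with the stricter filter.

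Among lists tied to the study, KLF and SP family genes fell in 12 of 23 cases and rose in 5 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0401, but adjusted p = 0.337 with an estimated correlation). KLF3 (-1.68, SE 0.03), KLF17 (-2.60, SE 0.05), KLF10 (-0.77) and KLF13 (-0.58) fell, while KLF18 (0.89), KLF5 (0.23), SP6 (1.08) and KLF2 (0.23) rose. In this fit, list KLF_SP_family KO1 vs WT, leaving out WT replicate 1, KO1 replicate 1 or KO1 replicate 3 gave an adjusted p of 0.0573, 0.0558 and 0.0514, and the stricter filter gave 0.0681. Muscle differentiation genes rose in 10 of 24 cases and fell in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.047, but adjusted p = 0.233 with an estimated correlation), among them FBXO32 (0.83), CKMT2 (0.55), MYH3 (0.57) and CKM (0.95), against MEF2C (-0.33) and ENO3 (-0.14; -0.09 and not called without WT replicate 3). The fit of list muscle_differentiation KO1 vs WT gave adjusted p = 0.0573 without WT replicate 1, 0.0587 without WT replicate 3, 0.0516 without KO1 replicate 2, 0.0729 without KO1 replicate 3, 0.0519 with the replicate number as a block, and 0.0681 with the stricter filter. DUX4 targets split by calls, with 30 higher and 32 lower of 75 (31 and 33 adjusted over the list alone, camera adjusted p = 0.309). By 2-fold, 11 were lower and 3 higher, with a median log2 change of -0.06 and a mean of -0.40. The 3 higher were FRG2B and the DEFB103B copies, all from multicopy families. TPRX1 fell (-3.29, SE 0.04) along with CCNA1, ALPG and CA2, whereas FRG2B (1.35, SE 0.04), TRIM49B (0.82), PRAMEF26 (0.49) and PRAMEF25 (0.43) rose. Myoblast genes were 10 higher and 12 lower of 23 (10 and 12 adjusted over the list alone; camera adjusted p = 0.198), with FGFR4 (-1.59), MYOD1 (-1.56) and MET (-0.76) lower and CHRNA1 (0.30), ITGA7 (0.26) and VGLL2 (0.51) higher. Fibroblast and matrix genes were 10 higher and 14 lower of 29 (10 and 14 adjusted over the list alone; camera adjusted p = 0.805). COL6A1 (-0.81), PDGFRB (-0.90), COL6A2 (-0.50) and SPARC (-0.42) fell, while POSTN (1.03), ELN (1.60), FAP (0.88) and FBLN1 (0.69) rose. The remaining lists did not pass, with adjusted p from 0.198 to 0.902.

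The Short clones were compared with KO1. The largest rises were genes almost silent in KO1. KISS1R, the kisspeptin receptor, went from 1.88 to 27522 normalized counts (log2 fold change 13.47, SE 0.28, adjusted p = 2.59e-21). P2RX1, an ATP-gated channel (11.84, SE 0.42), NPR1, a natriuretic peptide receptor (11.12, SE 0.28), TSPAN32 (10.47), LINGO1 (9.84), CA4 (9.41) and FOXF2 (8.96) also rose. NTSR1 had 0 reads in KO1 and was at least 850.6-fold higher. KCNK15, NDNF, HEPACAM and ADGRG3 had 1 read each over the KO1 libraries, with ratios of 4861 (95% interval 872 to 191987) for KCNK15, 2882 (517 to 113816) for NDNF and 2144 (385 to 84693) for ADGRG3, and an interval of 392 to 86177 for HEPACAM. The largest falls were B4GALT6 (-6.02, SE 0.33), CPZ (-5.45), ZNF737 (-5.44), OCIAD2 (-5.41), UCHL1, a ubiquitin hydrolase of neurons (-5.32), PADI2 (-5.29), ZSCAN18, ZNF718, SELENBP1, ZNF135, H3-7 and VWA1 (-4.63). In all 15079 genes were called, 7664 higher and 7415 lower, and 3309 were higher and 1170 lower by 2-fold. The listing of genes by signal over all lines can favour rises against KO1, here and with the Long form. Short clone 1 and Short clone 2 gave 14939 and 14121 calls on their own.

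The Long clones were compared with KO1 in the same way. KISS1R (log2 fold change 14.13, SE 0.28, adjusted p = 6.44e-22), NPR1 (12.03), P2RX1 (11.85), TSPAN32 (11.31), LINGO1 (10.70) and CA4 (10.29) were again among the largest rises. COL2A1, a cartilage collagen, went from 10.6 to 38635 normalized counts (11.17, SE 0.16). NTSR1 was at least 2280.2-fold higher. NDNF, CARMIL3 and ADGRG3 had 1 KO1 read each and ratios of 10179 (1827 to 402060), 3936 (706 to 155462) and 3585 (644 to 141617), and HPCAL4 had 3 and a ratio of 2510 (859 to 12172). The largest falls were UCHL1 (-5.90, SE 0.18), PADI2 (-5.52), MS4A6E (-5.26), PRPS2 (-4.78, SE 0.07), ZNF718, ZNF737, ZSCAN18, VWA1, MSL3B, LAMP5, SYPL2 and MEG3 (-3.84). In all 15832 genes were called, 8093 higher and 7739 lower, and 4086 were higher and 2082 lower by 2-fold. Long clone 1 and Long clone 2 gave 15930 and 14717 calls on their own. By 2-fold, 4651 genes were higher and 2906 lower in Long clone 1, against 3576 and 1221 in Long clone 2.

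DUX4 targets moved both ways in both forms. Of 75, 30 rose and 33 fell with the Short form (30 and 33 adjusted over the list alone; camera adjusted p = 0.756), and 31 rose and 35 fell with the Long form (31 and 35 adjusted over the list alone; camera adjusted p = 0.856). The Short list's median was 0 and its mean 0.47. CCNA1 (4.17 with Short, 4.31 with Long), TPRX1 (5.69 and 5.88), ALPG (6.33 and 7.49) and CA2 (6.98 and 6.47) rose, whereas ZSCAN5C (-2.70 and -3.44), TRIM49B (-1.57 and -2.06), ZSCAN5B (-1.56 and -2.62) and RFPL4B (-1.12 and -1.76) fell, with SE from 0.02 to 0.07. KLF and SP genes rose in 12 cases and fell in 9 of 23 with Short (12 and 9 adjusted over the list alone; camera adjusted p = 0.49) and in 11 and 9 with Long (11 and 9 adjusted over the list alone; camera adjusted p = 0.856). KLF3 (4.25 and 4.64), KLF10 (2.58 and 2.50), KLF16 (2.09 and 2.49) and KLF17 (3.02 and 3.04) rose, and KLF5 (-0.80 and -1.69), KLF2 (-0.99 and -1.49), KLF6 (-0.85 and -1.80) and KLF9 (-0.79 and -1.08) fell. KLF18, the gene added to these clones, rose by 2.60 with Long and stood at 4.66 and 2.76 times KO1 in Short clones 1 and 2.

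Myoblast genes rose in 13 and fell in 9 of 23 cases with Short (13 and 9 adjusted over the list alone; camera adjusted p = 0.756) and in 12 and 8 with Long (12 and 8 adjusted over the list alone; camera adjusted p = 0.856). MYOD1, the muscle-determining factor, rose by 4.07 with Short and 4.17 with Long (SE 0.06 each), with DES (1.35 and 1.21), EYA1 (3.45 and 4.37), DAG1 with Short (0.68) and FGFR4 with Long (1.97), while ITGA7 (-0.88 in both), VGLL2 (-1.74 and -2.35), CHRNA1 (-0.47 and -0.74), MSTN with Short (-3.64) and NCAM1 with Long (-0.89) fell. Muscle differentiation genes were 10 higher and 10 lower of 24 with Short (10 and 10 adjusted over the list alone; camera adjusted p = 0.756) and 9 and 12 with Long (9 and 12 adjusted over the list alone; camera adjusted p = 0.806). ACTC1 (-2.21 and -2.34), KLHL41 (-1.36 and -2.19), TNNT2 (-2.55 and -2.52), FBXO32 with Short (-1.01) and CKMT2 with Long (-1.66) fell, and TNNT1 (4.83 and 5.47), CKM (4.16 and 5.24), TNNT3 (3.27 and 4.37) and ENO3 (0.78 and 0.76) rose. Of 29 fibroblast and matrix genes, 12 rose and 13 fell with Short (12 and 13 adjusted over the list alone; camera adjusted p = 0.946), and 11 rose and 14 fell with Long (11 and 14 adjusted over the list alone; camera adjusted p = 0.799). COL6A1 rose from 22517 to 309540 and 465509 normalized counts, with PDGFRB (2.45 and 3.17), LOXL1 (0.95 and 1.41), COL6A3 with Short (1.37) and TWIST2 with Long (4.03), against falls of ELN (-2.69 and -2.97), PDGFRA (-1.49 and -2.36), COL3A1 (-1.34 and -1.87) and COL5A2 (-0.50 and -1.10). Genes given above for a single form were among the listed members of that form only. Their values with the other form are not given, so these changes are not thereby particular to a form.

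Cell-cycle genes rose in 33 of 38 cases and fell in 3 with the Short form (33 and 3 adjusted over the list alone; camera adjusted p = 4.54e-05, but adjusted p = 0.381 with an estimated correlation). CCNE1 (log2 fold change 1.72, SE 0.03), RRM2 (1.42), CDC20 (1.64) and UBE2C (0.81) led, and MCM7 (-0.43), PCNA (-0.11) and MCM6 (-0.14) were lower. PCNA (-0.07) and MCM6 (-0.09) lost the call without KO1 replicate 1, and MCM6 stood at 0.05 in Short clone 1 alone. With the Long form 13 rose and 12 fell (camera adjusted p = 0.975). Histone genes fell in 13 of 13 cases with Long (13 adjusted over the list alone; camera adjusted p = 0.0418, but adjusted p = 0.153 with an estimated correlation), led by H2BC12 (-1.91), H2BC5 (-2.73), H2BC11 (-1.26) and H2AC6 (-0.98). The fit of list histone_replication Long vs KO1 gave adjusted p = 0.0535 without KO1 replicate 1 and 0.141 with the stricter filter. By clone, histone genes were called in Long clone 1 vs KO1 (adjusted p = 0.0292) and Short clone 1 vs KO1 (0.0166), and not in Long clone 2 vs KO1 (0.117) or Short clone 2 vs KO1 (0.172), and neither call held with an estimated correlation (0.125 and 0.134). With both Short clones 10 of 13 fell (camera adjusted p = 0.0613). Adjusted p for the lists not named here ran from 0.0686 to 0.998 with Short and from 0.155 to 0.975 with Long.

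Both forms changed largely overlapping sets. Of the 3309 genes 2-fold higher with Short, 3169 were also 2-fold higher with Long, against 728.5 for independent lists, and of the 1170 lower, 969 were also lower, against 131.3. The log2 fold changes correlated across genes with r = 0.96, where genes are not independent replicates. Both comparisons use the same KO1 libraries, and 20 simulations without effects gave r = 0.67 and an overlap of 0. Without effects hardly any gene can pass the thresholds, so that overlap was fixed beforehand and decides nothing. The covariance was 2.063 against 0.014 simulated. With separate KO1 libraries for each form, 1 in the one comparison and 2 in the other, the 6 divisions gave overlaps of 3066 to 3125 higher and 934 to 951 lower genes and r = 0.94. Of the 506 genes 2-fold lower in KO1 than in WT, 335 were 2-fold higher with Short and 337 with Long, against 90.2 and 111.4 for independent lists, and 26 and 24 fell by a further 2-fold. Of the 649 higher in KO1, 229 with Short and 217 with Long were lower again, against 40.9 and 72.8, while 144 and 195 rose by a further 2-fold. For these pairs the covariance was -0.227 against -0.014 simulated, and r was -0.31 and -0.26 against -0.58 simulated. With separate KO1 libraries, r ran from -0.29 to -0.26 for Short and from -0.25 to -0.21 for Long.

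The question in the series title is how the Long and Short forms differ. With the mean of both Long clones against both Short clones, B4GALT6, a glycosphingolipid synthesis enzyme, was higher with Long (423 against 3.77 normalized counts; log2 fold change 4.70, SE 0.27, adjusted p = 1.14e-12), but Long clone 1 had 831 and Long clone 2 had 14.9. OCIAD2 (4.17, SE 0.13), BCHE (3.88), ASS1 (3.72), LANCL3 (3.47), HOXB-AS4 (3.40), IGFN1 (3.37), CPZ (3.22), TMEM271 (3.19), ECEL1 (2.99) and NKX1-1 (2.89) followed. MS4A6E (-5.44, SE 0.22), MSL3B (-4.03), PRPS2 (-4.02, SE 0.06), PCOLCE2 (-3.42), LINC01876 (-3.42), CEP15 (-2.88), XYLT1 (-2.72), TRIML2 (-2.60), HTR1A (-2.58), CXXC4-AS1 (-2.46), ZNF726 (-2.29) and NXPH1 (-2.22) were lower. In all 12813 genes were called, 6786 higher and 6027 lower, and 915 were higher and 174 lower by 2-fold. These p-values measure the spread between libraries of a clone. With 1 mean profile per clone, 2 against 2, limma called 0 genes (smallest adjusted p = 0.649), with 1206 genes at an unadjusted p under 0.05 (6.5% of genes). Both Long clones lay on 1 side of both Short clones for 7708 of 18559 genes. Long clone 1 and Short clone 1 lay on 1 side of the others for 8513, and Long clone 1 and Short clone 2 for 2337, where an even share would be 33.3% each. Long vs Short calls held in all 4 clone pairs for 2557 genes.

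**Figure D2:**
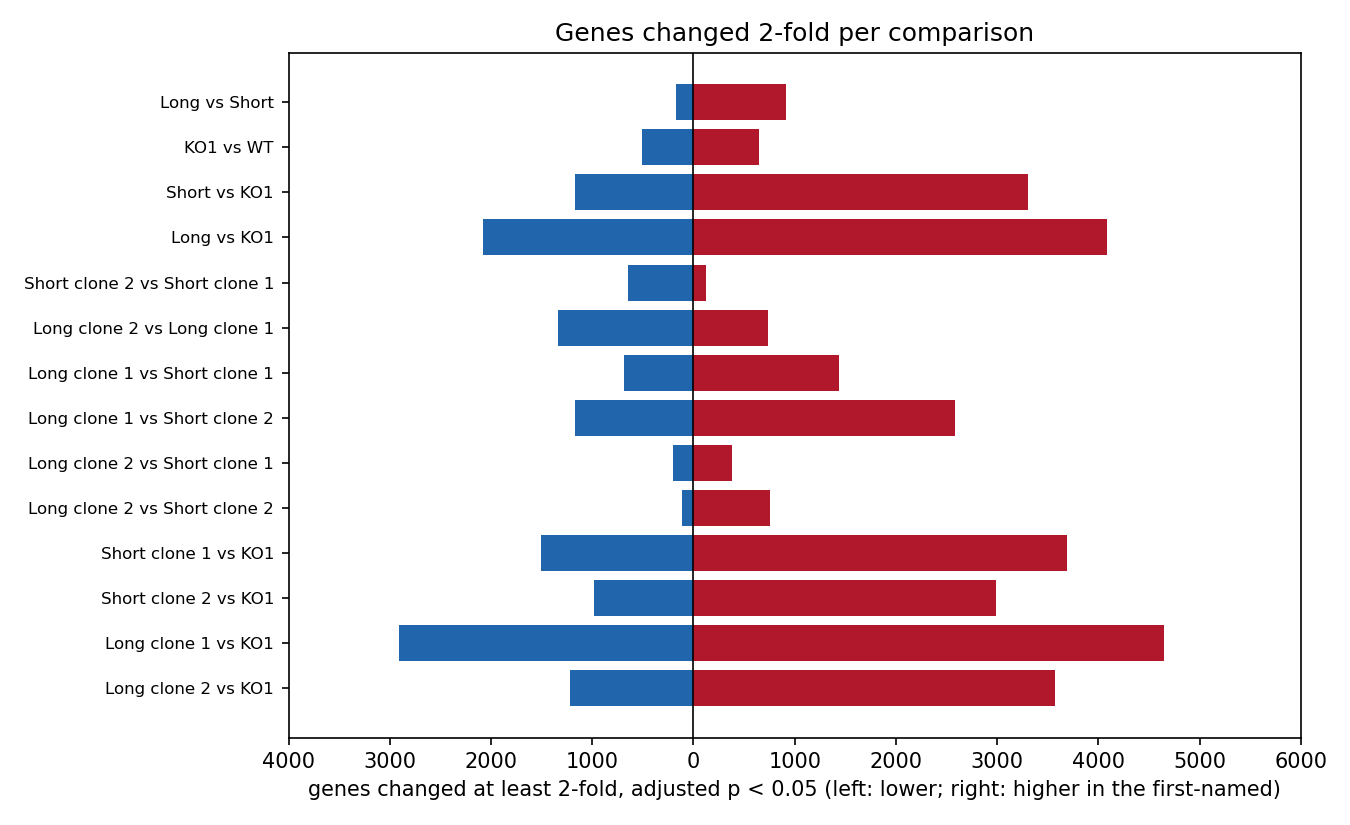
Genes changed at least 2-fold at adjusted p under 0.05 per comparison, with genes higher in the first-named line to the right and lower to the left. Long clone 1 against Short clone 2 gave 2586 higher and 1166 lower genes, and Long clone 2 against Short clone 1 gave 384 and 204.

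Cell-cycle genes were lower with Long in 35 of 38 cases and higher in 2 (35 and 2 adjusted over the list alone; camera adjusted p = 1.61e-12, but adjusted p = 0.171 with an estimated correlation), and camera placed them lower in each of the 4 clone pairs (adjusted p from 5.59e-17 to 2.84e-06, but from 0.0627 to 0.496 with an estimated correlation). The list also differed within forms, lower in Short clone 2 than in clone 1 (camera adjusted p = 0.000339) and higher in Long clone 2 than in clone 1 (camera adjusted p = 0.0104), again not with an estimated correlation (adjusted p = 0.563 and 0.639). CENPE (log2 fold change -0.93, SE 0.03), CDK1 (-0.71), CCNA2 (-0.69) and TOP2A (-0.53) fell, and RRM2 (0.13) and CCNE1 (0.07) rose, although both were lower in Long clone 2 vs Short clone 1 (-0.41 and -0.14) and CCNE1 (0.05) lost the call without Long clone 2 replicate 1. Immediate early genes fell in 16 of 20 cases and rose in 2 (16 and 2 adjusted over the list alone; camera adjusted p = 4.94e-05, but adjusted p = 0.333 with an estimated correlation), with JUN (-1.18, SE 0.02), CCN2 (-0.99), CCN1 (-1.26) and FOS (-0.88) lower and EGR3 (0.63) and NR4A2 (0.21) higher. The list was not called in Long clone 1 vs Short clone 2 (adjusted p = 0.146), and was called lower in the other pairs (0.0206, 4.81e-06 and 2.09e-09), but in none with an estimated correlation (0.174 to 0.596). In Long clone 2 vs Short clone 1 the direction turned for CCN2 (0.08), FOS (0.01), EGR3 (-0.49) and NR4A2 (-0.21), and in Long clone 2 vs Short clone 2 for EGR3 (-0.03).

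Fibroblast and matrix genes fell in 18 of 29 cases and rose in 9 (18 and 9 adjusted over the list alone; camera adjusted p = 0.0206, but adjusted p = 0.592 with an estimated correlation). POSTN (-0.82), PDGFRA (-0.87), COL5A2 (-0.60) and COL1A1 (-0.71) fell, and COL6A1 (0.53), LOXL1 (0.46), PDGFRB (0.73) and TWIST2 (1.11) rose. These rises turned to falls in Long clone 2 vs Short clone 1 (COL6A1 -0.31, LOXL1 -0.41, PDGFRB -0.50 and TWIST2 -0.38). The list was not called in Long clone 1 vs Short clone 2 (adjusted p = 0.146), was called in the other pairs (adjusted p = 0.0206, 1.06e-07 and 0.00997), and was also lower in Short clone 2 than in Short clone 1 (adjusted p = 0.0207). None of these calls held with an estimated correlation (0.175 to 0.596). Heat shock genes fell in 8 of 15 cases and rose in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0278, but adjusted p = 0.592 with an estimated correlation), with HSPA1A (-0.66), HSPH1 (-0.42), HSPA4L (-0.51) and HSPA8 (-0.46) lower and HSPE1 (0.21) higher. Of the clone pairs, only Long clone 2 vs Short clone 2 was called (adjusted p = 9.85e-05, but 0.176 with an estimated correlation, against 0.0769, 0.152 and 0.206 for the others). The fit of list heat_shock Long vs Short gave 0.0749 with the stricter filter, and HSPA4L (0.20) and HSPE1 (-0.15) turned in Long clone 2 vs Short clone 1. Hypoxia and glycolysis genes fell in 16 of 25 cases and rose in 5 (16 and 5 adjusted over the list alone; camera adjusted p = 0.039, but adjusted p = 0.592 with an estimated correlation), with P4HA2 (-0.50), ADM (-0.41), SLC2A1 (-0.48) and ENO1 (-0.28) lower and NDRG1 (0.47), CA12 (1.37), ANGPTL4 (0.54) and VEGFA (0.14) higher. The list was called for Long clone 2 (adjusted p = 3.66e-05 and 0.00209, but 0.175 and 0.176 with an estimated correlation) and not for Long clone 1 (adjusted p = 0.228 and 0.447). The fit of list hypoxia_glycolysis Long vs Short gave 0.132 with the stricter filter, and NDRG1 (-0.37), ANGPTL4 (-0.29) and VEGFA (-0.41) turned in Long clone 2 vs Short clone 1.

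DUX4 targets were 30 higher and 35 lower of 75 with Long (31 and 36 adjusted over the list alone; camera adjusted p = 0.348), and single clones disagreed. The list was higher in Long clone 2 vs Short clone 1 (adjusted p = 4.85e-06), lower in Long clone 1 vs Short clone 2 (adjusted p = 0.0499) and not called in the other pairs (adjusted p = 0.343 and 0.78). It was also higher in clone 2 than in clone 1 of Short (adjusted p = 0.000511) and of Long (adjusted p = 0.00639). None of these calls held with an estimated correlation (adjusted p from 0.411 to 0.869). ZSCAN5B (-1.06, SE 0.03), FRG2B (-0.91), RFPL4B (-0.63) and TRIM64 (-0.83) were lower with Long, and ALPG (1.16, SE 0.03), PRAMEF6 (0.38), PRAMEF10 (0.40) and PRAMEF5 (0.34) higher. FRG2B (0.09) and RFPL4B (0.09) turned in Long clone 2 vs Short clone 1, and TRIM64 (0.10) in Long clone 2 vs Short clone 2. Of 23 KLF and SP genes, 7 were higher and 12 lower (7 and 13 adjusted over the list alone; camera adjusted p = 0.359; median -0.09, mean 0.04), with KLF5 (-0.89), KLF6 (-0.95), KLF2 (-0.49) and KLF4 (-0.32) lower and KLF18 (0.75), KLF3 (0.39), KLF16 (0.40) and KLF15 (1.31) higher. Of 23 myoblast genes, 7 were higher and 10 lower (7 and 10 adjusted over the list alone; camera adjusted p = 0.578), with NCAM1 (-0.55), CDH2 (-0.35), VGLL2 (-0.62) and DAG1 (-0.28) lower and FGFR4 (1.28), PAX7 (2.26), EYA1 (0.92) and EYA4 (1.38) higher. The myoblast list was lower in Long clone 2 vs Short clone 1 (adjusted p = 0.0228) and in Short clone 2 vs Short clone 1 (adjusted p = 0.00244), but not with an estimated correlation (0.411 and 0.563). Of 24 muscle differentiation genes, 9 were higher and 8 lower (9 and 8 adjusted over the list alone; camera adjusted p = 0.578), with KLHL41 (-0.83), MYBPH (-0.55) and MYH2 (-0.99) lower and CKM (1.08), TNNT3 (1.10), TNNT1 (0.64) and FBXO32 (0.26) higher. Directions turned with the clone, for FBXO32 in Long clone 1 vs Short clone 1 (-0.13) and Long clone 1 vs Short clone 2 (-0.42), for KLHL41 (0.08), TNNT1 (-0.28) and the myoblast gene VGLL2 (0.12) in Long clone 2 vs Short clone 1, and for MYBPH (1.03) and MYH2 (0.06) in Long clone 2 vs Short clone 2. Adjusted p for the other lists ran from 0.0915 to 0.968. Among those, single pairs called histone genes in Long clone 1 vs Short clone 2 (0.0132) and the stress response, p53 target and NF-kB lists in Long clone 2 vs Short clone 2 (0.0215, 0.0451 and 0.0451), none with an estimated correlation (0.119 to 0.495). Histone genes were also higher in clone 2 than in clone 1 of Short (camera adjusted p = 0.00273) and of Long (0.0249). Cholesterol synthesis genes were higher in Long clone 2 than in Long clone 1 (camera adjusted p = 0.0437). These calls were lost with an estimated correlation (0.0742, 0.216 and 0.639).

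Clones of 1 form also differed from each other, and single-clone pairs across the forms ranged from 588 to 3752 genes changed 2-fold. Short clone 2 against Short clone 1 gave 10011 calls, 4614 higher and 5397 lower, with 122 higher and 649 lower by 2-fold. LYN, a Src-family kinase, was higher in clone 2 (2.78, SE 0.20), with C14orf132, IGFBPL1, FCN2, FXYD6, FXYD6-FXYD2, NHLH2, FGG, ITM2C, LINC02377, SLC35F3 and A2M (1.57). CALML5 (-2.62, SE 0.32), GRM4 (-2.61), LGR6, SIGLEC9, CHRDL2, HAPLN2, LCN10, CACNA2D3, FOXS1, COL2A1 (-2.16), DUSP9 and SYT7 (-2.11) were lower. Long clone 2 against Long clone 1 gave 12427 calls, 6249 higher and 6178 lower (7720 and 4954 when Long clone 2 vs Long clone 1 was scaled to library totals), with 737 higher and 1342 lower by 2-fold. EXD2 (4.74, SE 0.42), ZDHHC12 (3.93), LINC01060, ZNF726, LINC01592, PCOLCE2, HTATIP2, CDO1, POT1-AS1, TRIML2, CXADR and FAM180A (3.09) were higher in clone 2. B4GALT6 (-5.84, SE 0.38), SOD3 (-5.81), ZMAT4 (-4.18), SHROOM4, LANCL3, SELENBP1, CADM3, PRPS2, HSPB7, TMEM271 and CCDC149 (-3.48) were lower, and CEP15, with 2 reads over the Long clone 2 libraries, was lower by a ratio of 79 (95% interval 22 to 650). B4GALT6, LANCL3, TMEM271, PRPS2, CEP15, PCOLCE2, TRIML2 and ZNF726 are named both here and between the forms.

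**Figure D3:**
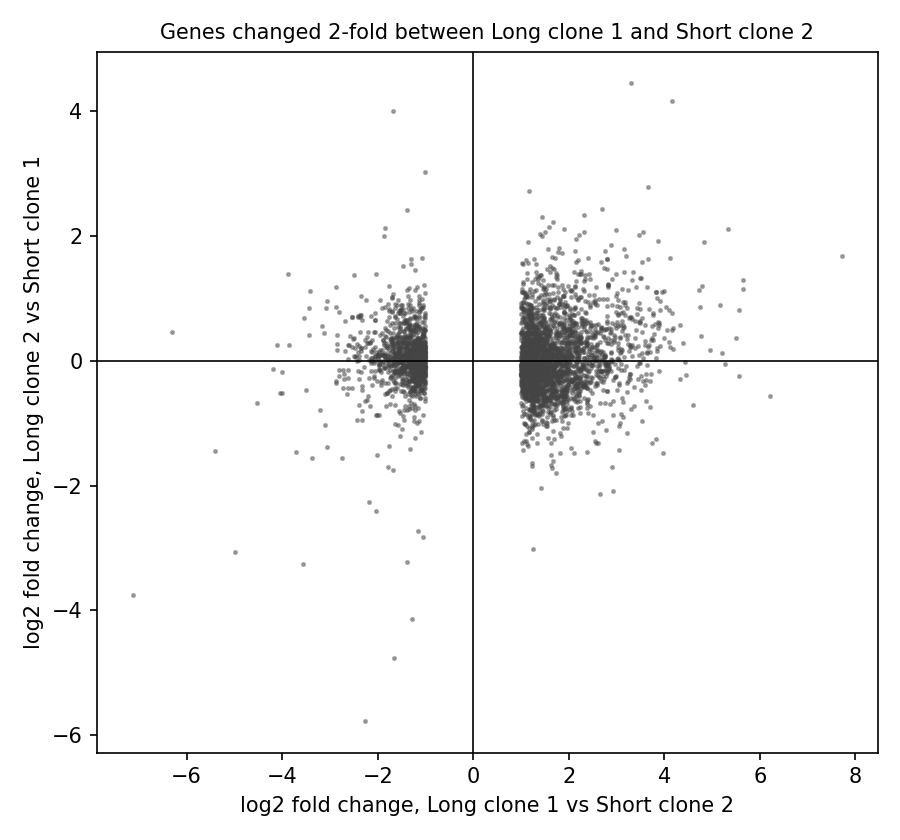
Each point is 1 of the 3751 genes changed at least 2-fold between Long clone 1 and Short clone 2, with that log2 fold change on the horizontal axis and the log2 fold change between Long clone 2 and Short clone 1 on the vertical axis. Genes on both sides spread around 0 vertically, with medians of 0.02 for the higher and 0.04 for the lower genes.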

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

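The tests of the KLF18 RNA level, of clone pairings, of genes lower in KO1 (separate KO1 libraries and matched genes) and of DUX4 targets were chosen after the results were seen, and the counts of other splits were planned. KLHL30 and TMEM119 stood out because the Short and Long forms moved them in opposite directions against KO1. KLHL30 changed by -1.07 with Short and 1.18 with Long on the log2 scale, so the difference of 2.25 follows from how it was picked, and its p-value (limma adjusted p = 2.76e-14) covers libraries, not clones. Its means were 60.9 and 22.2 normalized counts in the Short clones and 335 and 95.5 in the Long clones, against 77.9 in KO1. TMEM119 changed by -1.06 with Short and 1.05 with Long, a difference of 2.11 (limma adjusted p = 6.71e-08) to which the same applies. Its means were 11.9 and 7.8 in the Short clones and 53 and 36.1 in the Long clones, against 20.9 in KO1. These were the 2 genes that passed 2-fold both ways.

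The first pattern is the difference between Long and Short clones. Long clone 1 and Short clone 2 differ 2.74-fold in KLF18 RNA, and 3751 other genes changed 2-fold between them, with a median signed log2 change of 1.47. In the independent libraries of Long clone 2 and Short clone 1, which differ 1.04-fold in KLF18, the same genes had a median signed change of -0.02 (-0.05 to 0.01 over 9 library pairs), which argues against the form as the whole cause; 196 of them were called 2-fold the same way and 87 the other way. The KLF18 RNA level may be a part cause, and by these counts it is not the whole. Between Long clone 2 and Short clone 1, 588 genes differed 2-fold. By the authors' fold changes, 165 genes were higher and 148 lower by 2-fold in Long clone 2. At similar KLF18 ratios, pairs with Long clone 1 gave more genes changed 2-fold. These were 2079 against Long clone 2 (ratio 1.56) and 2118 against Short clone 1 (1.62). Pairs without it gave 771 between the Short clones (1.69) and 866 between Long clone 2 and Short clone 2 (1.75). The 3751 genes were picked in a pair with Long clone 1. A deviation of that clone alone would also leave their median small in the other pair. KLF18 counts are not corrected for the length of a form, so equal counts need not be equal levels in Short and Long. Clone differences stay open: Long clone 1 and Short clone 1 against the remaining clones gave 1114 genes past 2-fold (801 with the clones apart), against 1089 (879) for the forms and 163 (83) for Long clone 1 and Short clone 2 against the rest. A difference by form also stays open. In all 4 clone pairs, which share libraries, 126 genes were higher and 24 lower by 2-fold, a set picked from these same data.

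The second pattern is that genes lower in KO1 than in WT were higher in the clones, 309 of 506 with both forms. With separate KO1 libraries for the comparison with WT and for those with the clones, 295 to 349 genes did so in 6 divisions, against at most 98.1 for independent lists, which argues against error in the shared libraries as the cause. This covers error of single libraries only, since a deviation common to all KO1 libraries stays shared in every division. Genes matched on their KO1 level were also often higher, but the share was 61.1% here, against a median of 37.4% and a highest value of 41.1% over 100 matched draws, which argues against a general rise at these levels as the whole cause. That reading rests on the spread of the draws, taken up after a margin of 1.5 times the highest draw had been narrowly missed at 1.49. The listed genes all had a mean signal of at least 9.18 over all lines, most of them clones. Genes low in KO1 may therefore be listed because they are high in the clones, which can raise the matched share without a general rise. How far it did was not tested, and a general rise stays open as a part. An effect of the added KLF18 forms, which the design names, stays open and untested, with 1 knockout line and KLF18 RNA above WT in it and in all clones.

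The third pattern is the split among DUX4 targets. A lower or higher DUX4 level in the clones would move its targets together. Of the members changed 2-fold, at least 37.0% went the minority way in each form. This share counts near-identical copies as separate members, and 53 of the 75 members belong to multicopy families. Outside these families, 7 members were 2-fold higher in both forms and 1 was lower. The share therefore rests mostly on members whose values are uncertain, and another DUX4 level stays open, also for the members that fell. On reads shared between near-identical copies the tests differ. Outside the multicopy families only 1 of 22 members, ZSCAN4, was 2-fold lower in both forms, against the 7 higher. The split thus lay mostly within the families, which goes with this explanation. A first version of the family pattern left out DEFB103, ALPG and ALPP and included CCNA1. It had counted 3 lower members and was corrected after that count was seen. A further test, added after that first count, summed the reads of each family with a target and more than 1 gene in the table, and 5 of 17 families were 2-fold lower in both forms (4 of 6 in an earlier choice of mostly fallen families), which a mere exchange of reads between these copies would not give. Loss of reads that fit several places is not covered by either test, so the fall of these families stays uncertain.

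Other splits of the same libraries were counted in fits with a group on each side. For Long against Short, 1 of 100 splits gave as many calls, the real one, with 6352 against at most 4787 in the others. Splits that divide the libraries of a clone widen the spread on each side, which lowers their calls beforehand. These counts therefore exclude neither a chance arrangement of clones nor a chance difference between clones. In the fit with a group per line, Long clone 1 and Short clone 1 against the remaining clones gave 12858 calls, against 12813 for the forms. Short against KO1 gave 13168 calls against at most 4555, and Long against KO1 13836 against at most 8887, each in 1 of 84 splits. For gene lists, 33 of 100 splits gave as many as the 4 lists for Long against Short (highest other 9), 66 of 84 as many as the 1 for Short against KO1 (highest other 6), and 61 of 84 as many as the 1 for Long against KO1 (highest other 5), so chance cannot be excluded for these list counts. Splits of 3 against 3 libraries number 10, too few for a share under 0.05: the real counts were 9385 for KO1 against WT, 10352 between Short clones and 12825 between Long clones, with a highest other of 0 in each, and 8 lists against 5 for KO1 and WT, each as large in 1 split.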

How the results depend on the processing

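Choices listed as added were made after seeing the data; all others were fixed before. Of the alternatives for the 10 main counts, 164 stayed within 1.5 times and 21 moved, and of those for named genes and lists 8860 kept direction and call, 328 lost it, 23 gained it and 41 reversed. Changing the pseudocount, the scaling or the test per gene left every count of genes within 1.5 times: edgeR and DESeq2 on recovered reads gave 13015, 13006 and 12171 calls for Long vs Short and 10248, 10249 and 9275 for KO1 vs WT.

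With a 2-fold threshold the counts were 1089 for Long vs Short, 1155 for KO1 vs WT, 4479 for Short and 6168 for Long vs KO1, 771 between Short clones and 2079 between Long clones, by construction. For Long vs Short, 1 mean profile per clone gave 0 calls, with 2 profiles on each side, while 6 libraries against 6 gave 6352, calls in all 4 clone pairs 2557, and the authors' deposited calls in all 4 pairs 2378. Fry called 24, 22, 25 and 24 lists for Long vs Short, KO1 vs WT, Short vs KO1 and Long vs KO1, since it tests each list on its own, and camera with an estimated correlation called 0, 3, 0 and 0. With the stricter filter, which keeps 14353 genes, 3 lists passed the test for Long vs Short, where heat shock and hypoxia were lost, and 0 for Long vs KO1, where histone genes were lost; the cause was not tested.

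Leaving out 1 library at a time gave 12381 to 12571 calls for Long vs Short, 9552 to 10054 calls for KO1 vs WT, 14459 to 14935 calls for Short vs KO1, 15408 to 15764 calls for Long vs KO1, 9090 to 9339 calls for the Short clones, 11630 to 11863 calls for the Long clones. The lists past the test were 5 to 5, 8 to 10, 1 to 1 and 0 to 1 in the same order.

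Reversals fell almost all in Long vs Short and depended on the clone; the cause was not tested. In Long clone 1 against Short clone 1, log2 changes were FBXO32 -0.13. Against Short clone 2, log2 changes were FBXO32 -0.42. In Long clone 2 against Short clone 1, log2 changes were FRG2B 0.09, RFPL4B 0.09, RRM2 -0.41, CCNE1 -0.14, COL6A1 -0.31, LOXL1 -0.41, PDGFRB -0.50, TWIST2 -0.38, HSPA4L 0.20, HSPE1 -0.15, NDRG1 -0.37, ANGPTL4 -0.29, VEGFA -0.41, CCN2 0.08, FOS 0.01, EGR3 -0.49, NR4A2 -0.21, KLHL41 0.08, TNNT1 -0.28, VGLL2 0.12. In Long clone 2 against Short clone 2, log2 changes were TRIM64 0.10, EGR3 -0.03, MYBPH 1.03, MYH2 0.06, KLF17 -0.22. In Short clone 1 against KO1, log2 changes were MCM6 0.05. Without Long clone 1, an added setting, log2 changes were TRIM64 0.04, RRM2 -0.18, CCNE1 -0.01, COL6A1 -0.01, LOXL1 -0.07, PDGFRB -0.13, HSPE1 -0.02, NDRG1 -0.08, VEGFA -0.07, EGR3 -0.26, NR4A2 -0.04, MYBPH 0.44, KLF17 -0.16.

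Replicate numbers did not pair the libraries: deviations of same-numbered libraries had mean correlations from -0.04 to 0.09 over 15 pairs of lines, and 8 of 18 libraries were closest to their own number. With the replicate number as a block, Long vs Short gave 12825 calls and KO1 vs WT 10415. A filter on a total above 0 removes no gene and was not run, adjusted p-values were not recomputed from the authors' table because raw p-values were not used here, and rank tests and mean-signal filters on the authors' table, meant for a table without values per library, were not run.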

Other observations

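The genes and families below, and the tests on them, were chosen after their values were seen. Part of the KO1 difference from WT was still there in the clones. Of the 506 genes 2-fold lower in KO1, 110 changed 2-fold with neither form and 17 fell further with both. MEG3, an imprinted noncoding RNA, went from 2070 normalized counts in WT to 63.6 in KO1 and 1.4 to 4.9 in the clones. GPX7, an oxidized-protein peroxidase, went from 209 to 5.8 and then 1.4 to 2.8, and CTHRC1, a secreted matrix protein, from 918 to 86.7 and then 59.4 to 117. GYG2, a glycogen-priming enzyme, went from 101 to 9.3 and then 2.4 to 5.9. Other genes lower in KO1 went past WT: 199 stood 2-fold above WT with Short and 227 with Long. PITX1, a homeobox gene linked to DUX4, was at 163 in WT, 12.1 in KO1 and 3221 to 5572 in the clones, and LACC1 at 1563, 135 and 10293 to 14748. ODC1, the first enzyme of polyamine synthesis, ended near its WT level, at 83443, 8694 and 68676 to 102701. Of the 649 genes higher in KO1, 178 were 2-fold lower with both forms (27.4%, against a median of 4.9% in matched draws) and 138 rose further with both.

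Among 204 symbol families of at least 10 members, formed after the data were seen, the SPDYE family of cell-cycle activators rose in 18 of 18 cases with each form, with median log2 changes of 2.42 for Short and 3.04 for Long. Camera gave adjusted p = 0.000316 and adjusted p = 0.000246 at the preset correlation, and adjusted p = 0.131 and adjusted p = 0.0949 with an estimated correlation. These copies share sequence, so single members are uncertain.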
